A study of Mus musculus with 2 samples.

How the data were processed

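The data were 2 Agilent whole mouse genome arrays with 2 colours. On each array, RNA from Lamtor1-deficient (KO) CD4+ T cells was hybridised against RNA from wild-type (WT) CD4+ T cells. Per the labels, array 1 carried KO in Cy5 and WT in Cy3, array 2 carried the same pair with the dyes exchanged, and both were named as the same biological replicate. The 2 arrays were therefore counted as 1 replicate: there was 1 RNA extract per genotype, and the dye exchange repeats the labelling and hybridisation only. Both arrays lay on 1 slide, so slide was no batch.

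Per the labels' protocols, naive CD4+CD62L+ T cells of C57BL/6J mice were sorted magnetically from spleen and stimulated for 5 days with plate-bound antibody to CD3 and antibody to CD28, with IL-2 at 50 ng/ml and recombinant human TGFβ at 1 ng/ml. The extraction protocol in the labels speaks of naive cells. The RNA was taken here to come from the cultured cells, and the labels leave that open. Per the labels, 400 ng of each labelled cRNA was hybridised at 65 °C for 17 h.

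Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.3.1. The submitters' processing notes give version 10.5.1.1, and which of them applies was not settled. Per the file headers, the deposited scanner files hold each spot's mean intensity and the median intensity of its local background in both channels, with no correction. They also hold a processed intensity that the software had background-subtracted and dye-normalized by its linear and lowess method, per the file headers. The deposited series matrix holds log10 ratios of Cy5 over Cy3. All 44397 of its values per array equalled the scanner software's own log10 ratio within 0.000000001, which settled scale, direction and the absence of further centring; the median of each column was 0. Of these values, 9949 on array 1 and 12769 on array 2 were 0.

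Each array had 44397 spots, of which 1377 were control spots. The remaining 43020 spots carried 39429 probes, 399 of them spotted 10 times. No spot was saturated. Median signal was 71.4 (Cy3) and 70.5 (Cy5) on array 1 against a median local background of 38 and 42, and 68.5 (Cy3) and 76.4 (Cy5) on array 2 against 39 and 43. Of the non-control spots on array 1, 51.7% were well above background in the KO channel and 48.4% in the WT channel. On array 2 these shares were 43.7% and 48.8%. The 320 spike-in control spots had median signals of 59.0 (Cy3) and 53.7 (Cy5) on array 1, against 53.0 and 46.85 for the 153 negative control spots, and gave no usable calibration. The SD of the log2 ratio over the spots of a repeated probe had a median of 0.09 on each array.

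Mean signals were background-corrected with normexp (offset 50) and normalized by loess within each array, with limma 3.58.1 in R 4.3.3, with the package data.table in version 1.17.8; normexp used all spots, and control spots had weight 0 in loess and were then left out. Spots that the software marked as non-uniform or population outliers (206 on array 1 and 214 on array 2) were left out. Spots of the same probe were averaged. Ratios were turned to KO over WT by the dyes in the labels, and the mean of the 2 arrays was taken, in which a dye effect cancels. The ± beside a log2 ratio is the technical SD of the 2 arrays. An offset of 50 shrinks the ratios of dim probes. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

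Probe names came from the accession in the scanner files, matched without versions to the RefSeq gene table of the mouse assembly GRCm38.p6, which served for names only. Of the 39429 probes, 26055 were named by accession, 3195 by current symbol and 930 by a synonym, and 9249 kept the name in the file. Probe positions are those of the files, in build mm9. Of 31709 names, 6400 had several probes, and the brightest probe stood for the gene. Among the other probes of the genes past the rule of size below, 364 of 378 (96.3%) lay in the same direction on both arrays as the probe used. The 5 that lay in the opposite direction on both belong to Snhg16, Gm5523, Gm6981, 4930581F22Rik and an unnamed transcript. No probe was checked for cross-hybridisation to related genes.

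With 1 RNA extract per genotype no test was made and no p-value is given. A gene was called higher or lower in the KO extract by a rule of size: at least 2-fold in the same direction on each of the 2 arrays, with its probe well above background on both arrays in at least 1 of the RNAs. As a check for dye effects, genes at least 2-fold in the same dye direction on both arrays were counted as well. A gene not well above background in either channel of 1 RNA has only a bound: the bright RNA's mean against, per array, the higher of the lowest signal among probes well above background in that channel and the probe's own signal, per channel after loess and Aquantile normalization. Such genes are given as "at least N-fold".

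The 34 gene lists, the rule of size, the alternatives and the rule for naming genes were fixed before the data were examined. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean intensity in 20 bins (seed 1). A median outside the central 95% was called above or below, as a description of these 2 extracts. Most genes were named by a rule. It took Lamtor1 and the 12 highest and 12 lowest mean log2 ratios among genes past the rule of size, leaving out clone, predicted and RIKEN names. It also took up to 4 members of each list, first those past the rule of size and then the others, by size. The brightest members of marker lists of other cells were added. Genes outside this rule are named as well, among them Klra8, Klrb1c, Cd8a, Cd8b1, Sox13, Lyz1, Pik3ip1, Ddit4, Hbb-bt and those of the later tests.

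The procedure was tested on simulated data for the KO over WT comparison over 14870 genes. Every spot had the same noise SD, taken as the SD of the arrays' difference divided by 2, and a random dye effect of a set size. That SD describes the mean of 2 arrays, yet it was added to each array. The simulated arrays were therefore quieter than that difference implies, and the recovered shares may be too high. At the rule of size, 48 of 67 genes simulated at 3-fold (71.6%) and 57 of 66 at 4-fold (86.4%) were recovered, 0 of 67 at 1.5-fold were, and 0 of 14670 unchanged genes were called. Of 200 random lists of unchanged genes, 8 (4%) fell outside the random range. The real technical SD varied by gene, with a median of 0.11 and a 95th percentile of 0.33. With 1 small noise SD for all spots, the 0 unchanged genes called was close to fixed by the setting. The simulated genes were also independent, so the 4% does not describe lists of co-regulated genes. Alternatives changed the background correction, the normalization, the filter on dim probes, the outlier spots, the choice of probe, the source of values, the arrays used, the rule of size and the matching of random lists.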

Results

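Gene expression was compared between Lamtor1-deficient and wild-type mouse CD4+ T cells after culture with antibodies to CD3 and CD28, IL-2 and TGFβ, a cytokine that directs such cultures toward regulatory T cells. Lamtor1 is a subunit of the Ragulator complex, which anchors the kinase complex mTORC1 to the lysosome. The series title places the question in CD4+ T cell-mediated autoimmunity. The data were 2 arrays of the same pair of RNA extracts with the dyes exchanged, and 14872 genes or transcripts were measured. There was 1 extract per genotype, so no difference below has a check against biological replicates, and the number of arrays limits the precision.

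Lamtor1 was lower in the KO extract by 3.86-fold (log2 ratio KO over WT −1.95 ± 0.03, technical SD of the 2 arrays; −1.97 with KO in Cy5 and −1.93 with KO in Cy3). Its single probe lies at chromosome 7, 109060334 to 109060393 (mm9), and stayed well above background in the KO RNA on both arrays. Which part of the gene was deleted is not given in the sources used here. A probe outside the deleted part checks nothing about the labels. Across the genome, 366 genes were at least 2-fold higher and 1024 at least 2-fold lower in the KO extract on both arrays. After loess no gene was 2-fold apart in the same dye direction on both arrays. The log2 ratios of the arrays correlated with Pearson r = 0.939 and Spearman rho = 0.880 across genes, which are not independent replicates, and the median technical SD per gene was 0.11. With median centring in place of loess, 125 genes were 2-fold apart in the same dye direction and Pearson r was 0.731, so both depend on the normalization.

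**Figure D1:**
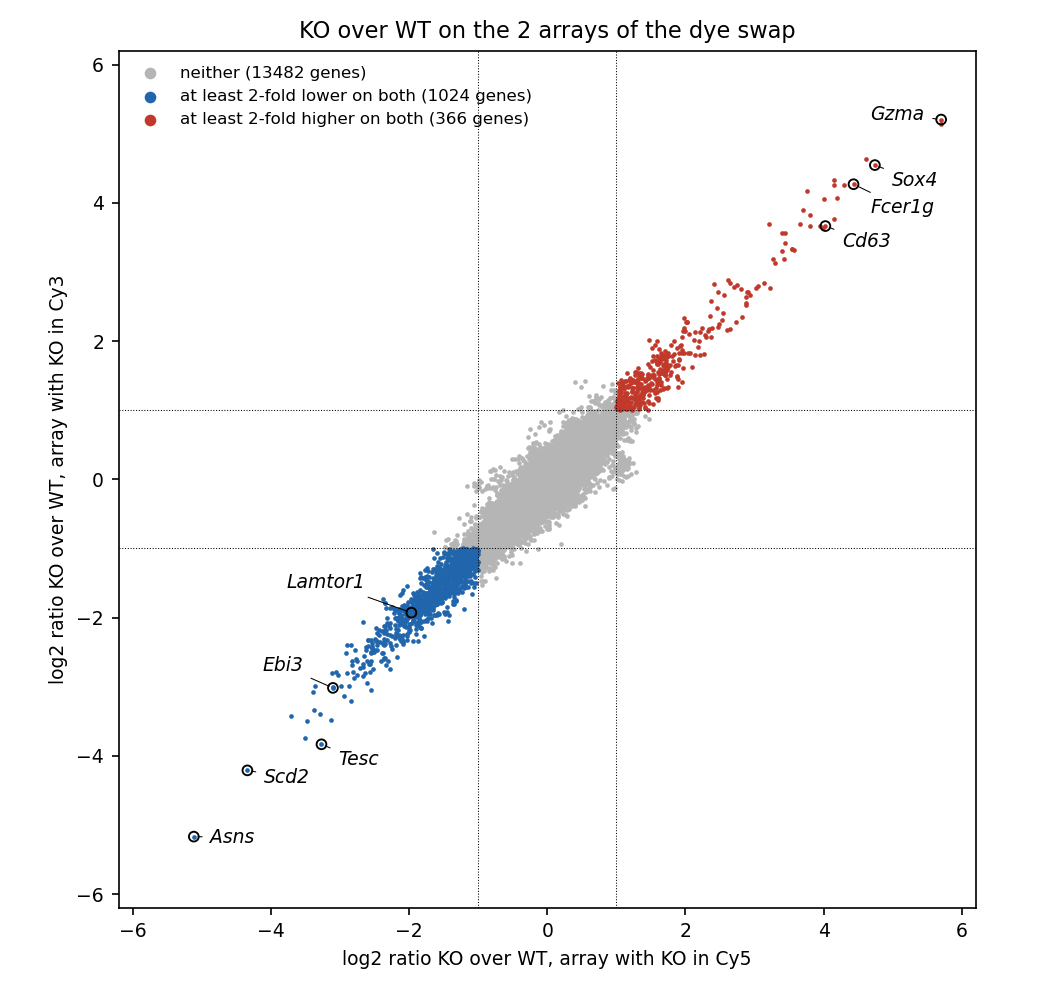
Each point is 1 of 14872 measured genes, placed by its log2 ratio KO over WT on the array with KO in Cy5 (horizontal) and on the array with KO in Cy3 (vertical); dotted lines mark 2-fold. The 366 genes at least 2-fold higher and 1024 at least 2-fold lower on both arrays lie along the diagonal, with Gzma at 5.45 and Asns at −5.14 as their means at the ends.

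The highest ratio belonged to Gzma, which encodes the cytotoxic protease granzyme A (43.8-fold, log2 5.45 ± 0.35; chromosome 13, 113884035 to 113884094). Fcer1g, the signalling chain of Fc receptors, stood at 4.35 ± 0.11, Itgae, the integrin αE chain that binds E-cadherin, was 18.4-fold higher, and the chemokine gene Xcl1 stood at 4.03 ± 0.03. Cxcr6, a chemokine receptor, stood at 4.24 and was well above background in the WT RNA on 1 of the 2 arrays. Further genes among the 12 highest were the transcription factor gene Sox4 (4.64), Ndrg4 (4.62), the calcium-binding protein genes S100a4 (4.28) and S100a9 (3.96, above background in WT on 1 array), Emp1 (4.13), the steroid dehydrogenase gene Akr1c18 (3.96) and Cd63 (3.84), a tetraspanin of late endosomes and lysosomes.

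At the other end, Asns, which encodes asparagine synthetase, was lower by 35.3-fold (log2 −5.14 ± 0.04; chromosome 6, 7625171 to 7625228). The desaturase gene Scd2 stood at −4.27 ± 0.09, the interferon-induced Ifi27l2a at −3.62, and Tesc at −3.55. Aldoc, a glycolytic aldolase, stood at −3.34, Dapl1 at −3.23, Tube1, which encodes epsilon-tubulin, at −3.17, Ebi3, which encodes a shared subunit of IL-27 and IL-35, at −3.06, and the transcription factor gene Atf5 at −3.03. Mgarp was not well above background in the KO RNA and was at least 10.2-fold lower there. Map6 (−3.57) and Trim12a (−3.30) were above background in KO on 1 of the 2 arrays. Their probes lie within 3 Mb of the Lamtor1 probe, and the 63 measured genes there, these included and Lamtor1 left out, had a median log2 ratio of −0.37 (−0.71 under median centring, or −0.34 relative to all measured genes).

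Lists of cell cycle, glycolysis, lipid synthesis and hypoxia genes had medians below 0. Of 39 measured cell cycle genes, 32 were at least 2-fold lower and 0 higher (list median −1.82), with Top2a, which untangles DNA, at −2.84, the CDK inhibitor gene Cdkn1a at −2.72, Ube2c at −2.63 and Cenpe at −2.62. Of 21 glycolysis genes 14 were lower and 0 higher (median −1.65), among them Pgk1 at −2.79, the lactate transporter gene Slc16a3 at −2.44 and Tpi1 at −2.00. Cholesterol synthesis and uptake had 14 of 24 lower and 0 higher (median −1.40), with Hmgcs1 at −2.43, Sqle at −1.98, Fdps at −1.94 and Pmvk at −1.88. The hypoxia response list had 9 of 15 lower and 0 higher (median −1.22), with Egln3 at −2.92, Bnip3 at −2.51 and Ankrd37 at −2.10. Fatty acid synthesis had 4 of 14 lower and 0 higher (median −0.72, or −0.64 with dim genes at their bound, the largest such shift of any list), with Mid1ip1 at −2.62 and Elovl6 at −1.61 beside Scd2. The medians of the first 4 of these lists lay below all 10000 random lists, and that of fatty acid synthesis at percentile 0.02.

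The lists of the Atf4, p53 and type I interferon responses also had medians below the random range. In the list of the amino acid response through Atf4, a transcription factor induced by amino acid shortage, 24 of 32 genes were at least 2-fold lower and 0 higher (median −1.52, percentile 0). Beside Asns and Atf5 these included the pseudokinase gene Trib3 at −3.03 and Psat1, of serine synthesis, at −2.93. Atf4 itself averaged −1.19 ± 0.40 and was not 2-fold lower on both arrays. The p53 response and apoptosis list had 8 of 19 lower and 0 higher (median −0.85, percentile 0), with Phlda3 at −2.75, Bbc3, a pro-apoptotic BH3-only gene, at −2.05 and Zmat3 at −2.04. Cdkn1a (−2.72) stands in both the p53 and the cell cycle list. The type I interferon response had 3 of 23 lower (Bst2 −1.85, Usp18 −1.64, Ifih1 −1.41) and 0 higher, with a median of −0.55 (percentile 0), which was −1.04 with the software's processed signals and −0.90 with a normexp offset of 1.

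**Figure D2:**
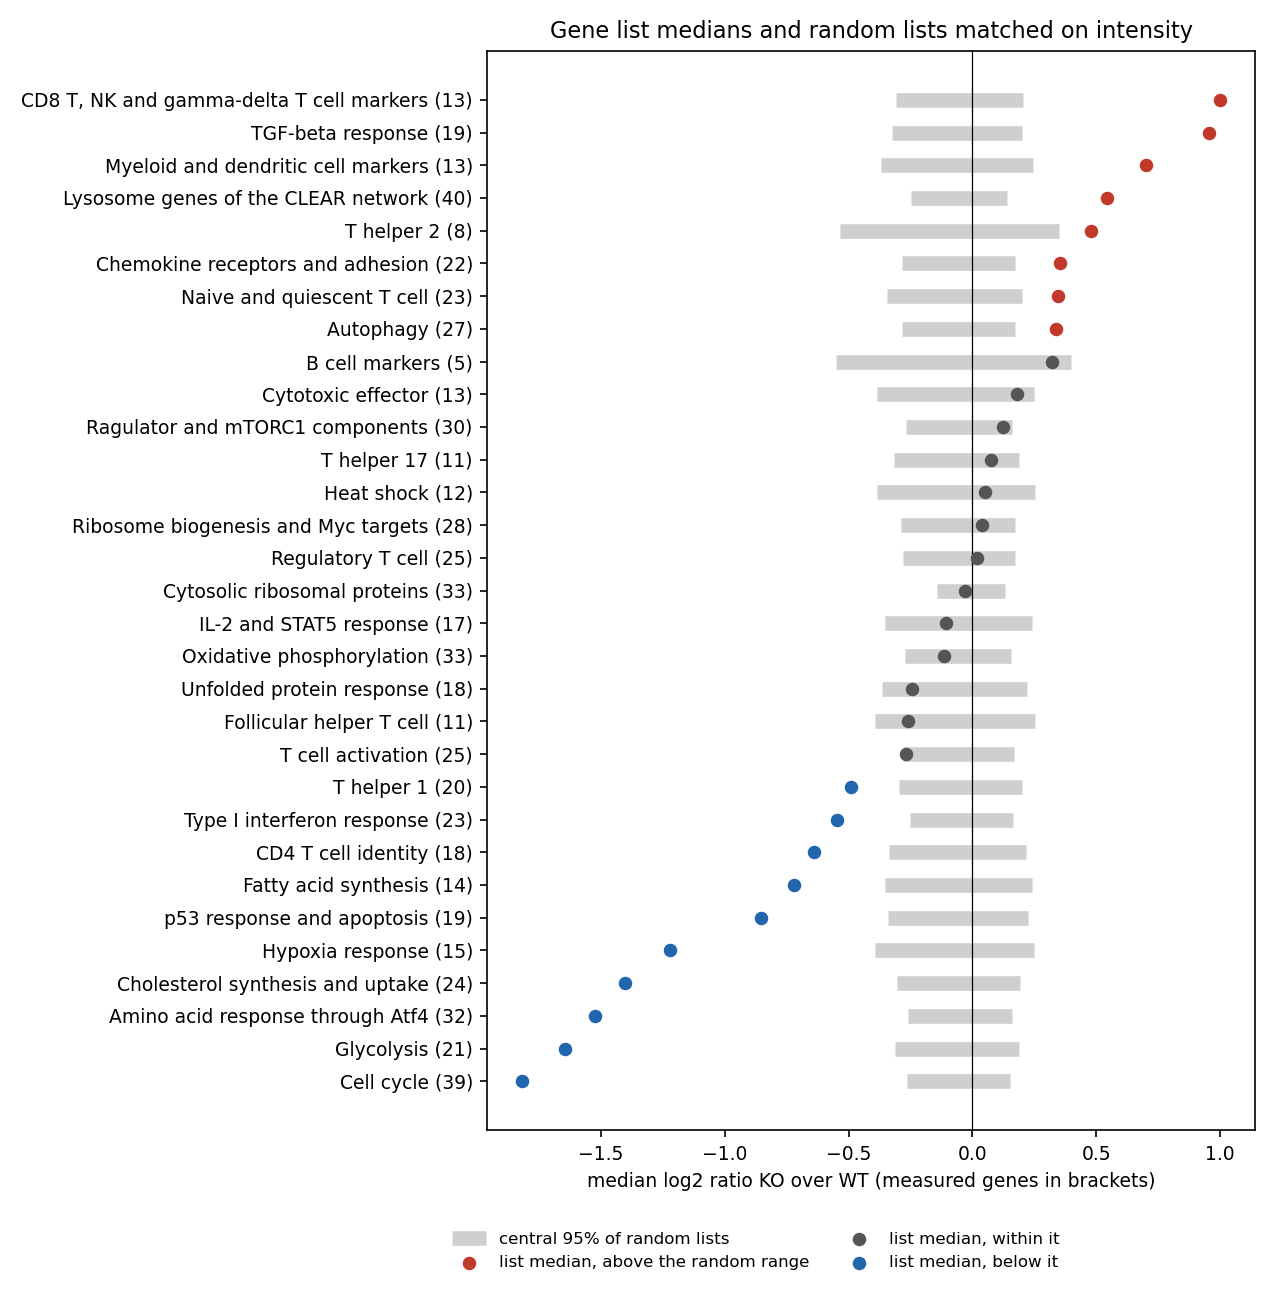
Points are the median log2 ratios KO over WT of 31 gene lists with at least 5 measured genes, and grey bars the central 95% of 10000 random lists of the same size matched on intensity. Medians of 10 lists lay below the random range, down to −1.82 for cell cycle, and 8 lay above it, up to 1.00 for the markers of CD8 T, NK and gamma-delta T cells; with median centring in place of loess the medians of the T helper 2, autophagy and naive lists were below 0 but still above the random range.

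Lysosome genes, in contrast, leaned higher in the KO extract. In the list of the CLEAR network, the lysosomal genes that TFEB-family factors bind, 5 of 40 genes were at least 2-fold higher and 0 lower, 26 lay above 0 and 12 below 0 on both arrays (median 0.54, above all 10000 random lists). Under median centring the list median was 0.09, or 0.47 relative to all measured genes. The 5 included Atp6v0a1 at 2.42 and Atp6v0d1 at 1.36, subunits of the proton pump that acidifies lysosomes, Cln3 at 1.33 and Ctsd, which encodes the protease cathepsin D, at 1.28. Of 27 autophagy genes 2 were higher and 0 lower, Gabarap (1.20) and Map1lc3b (1.12), both encoding proteins conjugated to autophagosome membranes; the list median of 0.34 (percentile 99.9) became −0.10 under median centring, where the median of all measured genes was −0.37, and 0.20 on the array with KO in Cy3 alone. Among 30 genes of Ragulator and mTORC1 components the median lay within the random range (0.12, percentile 94.1), and above it on the array with KO in Cy3 alone (0.17, percentile 98.55). Flcn, which encodes the Rag GTPase regulator folliculin, was higher at 1.86 ± 0.33, and Eif4ebp1 (−2.33), Sesn2 (−1.99) and Ddit4 (−1.74) were lower besides Lamtor1. Eif4ebp1 and Sesn2 also stand in the Atf4 list and Ddit4 in the hypoxia list.

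T cell genes went in several directions. Of 19 TGFβ response genes 8 were at least 2-fold higher and 2 lower (median 0.96, above all random lists; 0.62 under median centring, or 1.00 relative to all measured genes), with the receptor gene Tgfbr1 at 1.97, the feedback inhibitor gene Smad7 at 1.91, Itgae, and Ldlrad4, not well above background in WT and at least 3.43-fold higher. In the regulatory T cell list 5 of 25 were higher and 4 lower (median 0.02, percentile 66.65). That median had no stable sign, with −0.06 and 0.07 on the single arrays and −0.12 with the median over each gene's probes. The master transcription factor gene Foxp3 stood at 1.67 ± 0.31 and Ikzf4 at 1.72 ± 0.08, against Ebi3 at −3.06 and Ctla4, an inhibitory receptor gene, at −1.60. Of 18 CD4 T cell identity genes 4 were lower and 0 higher (median −0.64, percentile 0.06): Trat1 at −2.69, Cd4 at −1.18, Cd5 at −1.12 and Zbtb7b, the CD4-lineage factor ThPOK, at −1.03. Under median centring that median was −1.15, or −0.78 relative to all measured genes. The T helper 1 list had 6 of 20 lower and 1 higher (median −0.49, percentile 0.12), with Stat4 at −2.20, Ifngr1 at −1.54, Tbx21, which encodes T-bet, at −1.47 and Cxcr3 at −1.39; under median centring the median was −0.74, or −0.36 relative to all measured genes. Among 8 measured T helper 2 genes Ccr8 was higher (1.48), Ccr4 lower (−1.12) and Gata3 at 0.95 ± 0.35. The cytokine genes Il4, Il5 and Il13 were not measured, so the T helper 2 median of 0.48 (percentile 99.4) leaves them out. That median became −0.039 under median centring and lay within the random range with dim probes kept (percentile 93.9).

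Migration and quiescence genes also went both ways. Of 22 chemokine receptor and adhesion genes 7 were higher and 3 lower, with Ccr9, a gut-homing receptor gene, at 3.73 and Cx3cr1, not well above background in WT, at least 6.22-fold higher; the median of 0.35 (percentile 99.95) lay within the random range with no filter on dim probes (0.02, percentile 65.6) and with the stricter filter (percentile 62.4). It was 0.61 with the processed signals, and 0.07 under median centring, or 0.45 relative to all measured genes. Of 23 naive and quiescent T cell genes 6 were higher, among them Btg1 at 1.93 and Pik3ip1 at 1.51, and 3 lower, among them Dapl1 and Ly6c1 (−1.72). That list's median of 0.34 (percentile 99.9) became −0.19 under median centring and fell within the random range on the array with KO in Cy5 alone (percentile 91.75).

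Some markers of CD8 T, NK and gamma-delta T cells were higher in the KO extract, beside the lower Cd4. Of 13 measured markers in that list, 6 were at least 2-fold higher and 0 lower (median 1.00, above all random lists): Xcl1, the NK receptor genes Klrd1 (1.78) and Klrc1 (1.80), and Tyrobp, Klra8 and Klrb1c, which were not well above background in WT and at least 4.30-fold, 2.26-fold and 2.18-fold higher. Xcl1 also stands in the T cell activation list and Eomes (0.75, not called) in the T helper 1 list. Cd8a (0.67) and Cd8b1 (−0.55) were not called. The list median was 2.89 with the processed signals and 1.94 with an offset of 1. With the stricter filter on dim probes only 7 genes were left, and their median was 0.75. It was 0.92 with no filter, and both medians lay above the random range. Of 13 measured myeloid and dendritic cell markers, 5 were higher (Fcer1g, S100a9, S100a8, Tyrobp and Lyz1) and H2-Ab1, of MHC class II, was lower at −1.90 (median 0.70, above all random lists). S100a8 and Lyz1 were not well above background in WT and at least 4.92-fold and 2.97-fold higher. The brightest members of the myeloid list besides H2-Ab1 were Siglech (0.82), Itgam (0.70) and Cst3 (−0.49). Siglech and Itgam had mean log2 intensities of 14.1 and 12.8, near the 13.7 of the T cell gene Cd3d. Their probes were not checked for cross-hybridisation, so whether they report these myeloid genes is open. The list median of 0.70 is the value of Itgam. With the stricter filter on dim probes the list's median of 0.30 lay within the random range (percentile 95.8). It was 0.14 with no filter, and 0.18 under median centring, or 0.55 relative to all measured genes. Tyrobp stands in both marker lists. B cell markers had 5 measured genes and 0 called (median 0.32, percentile 95.05). Among them Cd79b stood at 0.62 and Cd24a at 0.38, the latter −0.02 under median centring. The B cell median lay above the random range on the array with KO in Cy3 alone (0.43, percentile 98.2). On the array with KO in Cy5 alone it lay within the range (0.21, percentile 83.4). It was 0.55 with the processed signals and 0.06 with no filter. Of the stromal and endothelial markers 3 were measured, Kdr, Sparc and Pecam1, with a median of 0.02, of the sex-linked genes only Xist (−0.37), and of the erythroid and platelet markers 0 under the names in the list, so these lists were not ranked. The beta-globin gene Hbb-bt, looked up after values were seen, was measured and at least 2.47-fold lower in the KO extract. It was not well above background there. The scanner file names its probe Hbb-b1, a member of the erythroid list. That probe lies within 3 Mb of the Lamtor1 probe, where genes leaned lower, so its ratio cannot be read as erythroid content alone.

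**Figure D3:**
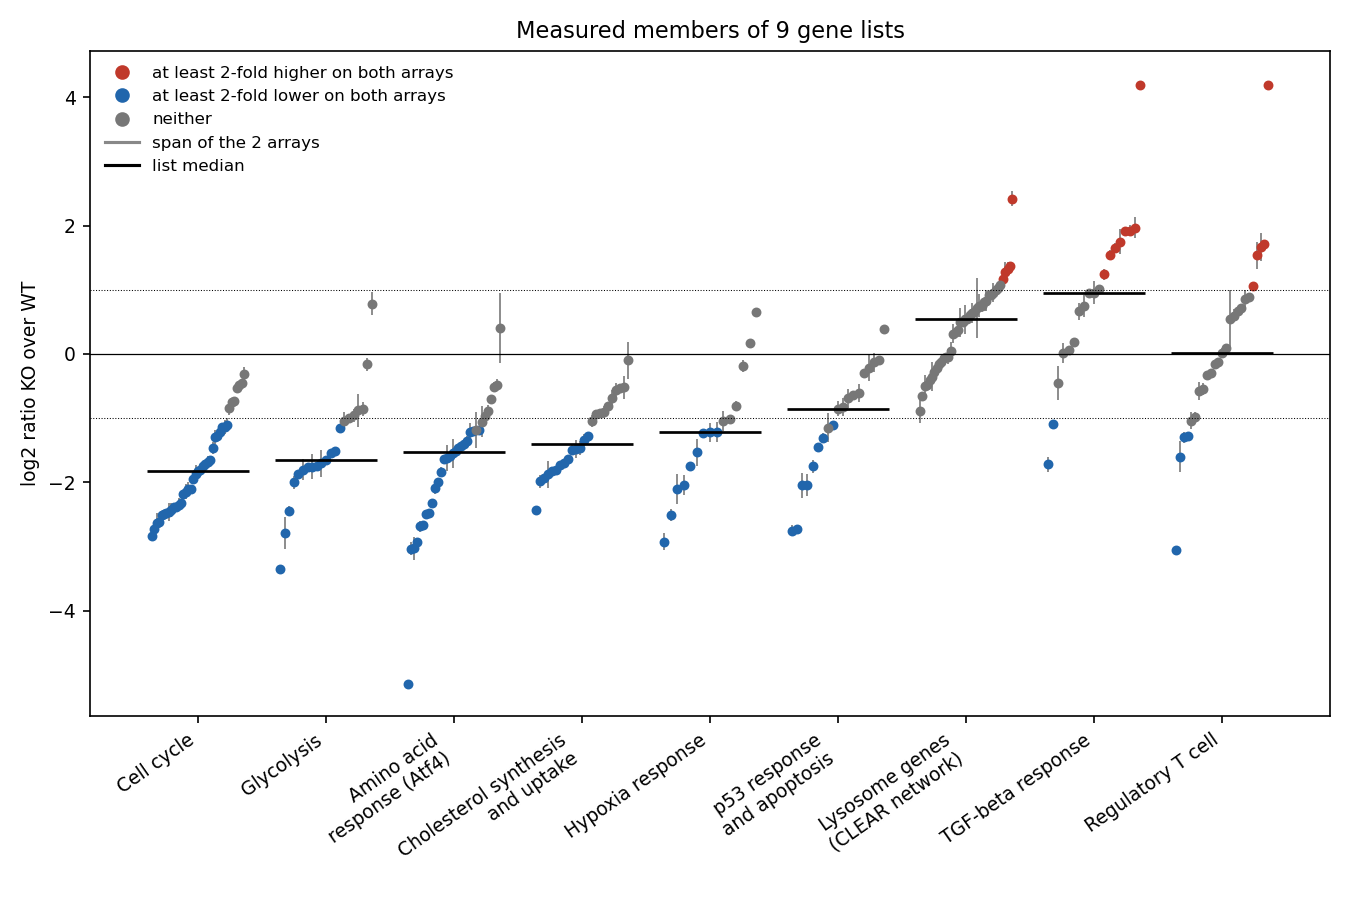
Each point is a measured member of 1 of 9 gene lists, at its mean log2 ratio KO over WT, and the grey line through it spans the 2 arrays; black bars are list medians and dotted lines mark 2-fold. Cell cycle, glycolysis, amino acid response, cholesterol, hypoxia and p53 lists lie mostly below 0 (medians −1.82 to −0.85), lysosome and TGFβ lists mostly above 0 (0.54 and 0.96), and the regulatory T cell list on both sides (0.02).

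The other lists had medians within the random range, and some held called genes. In the T helper 17 list Maf (3.48) and Ahr (2.59), both transcription factor genes, were higher and 0 of 11 lower (median 0.07, percentile 86.6). The cytokine genes Il17a, Il17f, Il21 and Il22 of that list were not measured, so this median leaves them out. With the stricter filter on dim probes 5 genes of that list were left, and their median of 0.65 lay above the random range (percentile 99.5); with no filter the median was −0.022. In the cytotoxic effector list Gzma and Gzmc (2.08) were higher and the protease inhibitor gene Serpinb6b (−2.67) lower among 13 (median 0.18, percentile 93.6). That median lay above the random range with an offset of 1 (0.37, percentile 97.54), under median centring (0.08, or 0.45 relative to all measured genes, percentile 99.8) and with no filter on dim probes (0.13, percentile 97.54). The follicular helper list had 3 of 11 higher, with Bcl6 at 1.89, and 2 lower, Sh2d1a (−2.85) and Btla (−2.22; median −0.26, percentile 9.98). That median lay below the random range with the processed signals and series matrix values (−0.97, percentile 0.38) and with an offset of 1 (−0.62, percentile 1.64), and turned to 0.32 within it with the stricter filter (percentile 97.3). T cell activation had 3 of 25 higher, among them Il3 at least 4.08-fold and Egr2 at 1.59, and 3 lower, among them Fos at −1.38; its median of −0.27 lay at percentile 2.84, and below the random range under 6 of 12 alternatives. The IL-2 and STAT5 response had 1 of 17 lower, Ctla4 (median −0.11, percentile 27.95). The unfolded protein response had 1 of 18 lower, Xbp1 at −1.22 (median −0.24, percentile 10.1). Heat shock had Hsph1 higher (1.19) and Bag3 lower (−1.23) among 12 (median 0.05, percentile 68.45). Ribosome biogenesis and Myc targets had Pes1 higher (1.22) among 28 (median 0.04, percentile 74.9), cytosolic ribosomal proteins Rps2 higher (1.15) among 33 (median −0.03, percentile 20.4), and oxidative phosphorylation 0 of 33 called (median −0.11, percentile 20.3). On the arrays with KO in Cy5 and in Cy3 alone, the median of the ribosomal proteins was 0.08 (percentile 71.6) and −0.18 (percentile 5.28), and that of ribosome biogenesis 0.0021 and −0.015.

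The counts depend on how background and dyes were handled. With the software's own processed signals 864 genes were higher and 1608 lower; with median centring 111 were higher and 881 lower.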

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

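Every alternative below was planned before the data were examined. No paired analysis was possible because there was 1 RNA extract per genotype and no test. Lamtor1 stayed lower under all 11 alternatives, at −2.18 with the software's processed signals and with the series matrix values (equal to them within 0.0001 for all 14869 measured genes), −2.02 with no background subtraction, −2.17 with a normexp offset of 1 and −2.39 with median centring. The genes higher in KO numbered 864 with the processed signals and with the series matrix values, 608 with an offset of 1, 111 with median centring, 1009 at 1.5-fold, and 428 to 556 on a single array; of the 366, 363 were also higher with the processed signals, 366 with an offset of 1, 110 with median centring and 366 at 1.5-fold. The genes lower in KO numbered 1608 with the processed signals and with the series matrix values and 2008 at 1.5-fold. At 1.5-fold the wider rule itself adds genes; for the others the cause was not tested. Genes higher made up 26.3% of called genes, 11.2% under median centring and 34.95% with the processed signals, the highest share among the changes of background correction and normalization. The limits for this share, 40% for and 35% against background correction or normalization as the origin of the uneven split, were set before it was seen. The share lay under 35%, so the limit against was met as it had been set. It lay under by less than the SD of the shares on the 2 single arrays (3.98), a margin that the limits as set did not hold. That SD describes the 2 arrays and not the changes of background correction and normalization. With so narrow a margin the question was left open. This test was taken out after its value was seen and then put back. Median centring moved the median of all measured genes from −0.02 to −0.37, and turned below 0 the medians of these lists called above the random range: autophagy (−0.10), naive and quiescent T cells (−0.19) and T helper 2 (−0.039). Relative to all measured genes they were 0.27, 0.19 and 0.34. Of the lists within the range it turned Ragulator and mTORC1 (−0.35), regulatory T cell (−0.54), heat shock (−0.47), ribosome biogenesis (−0.45), T helper 17 (−0.047) and B cell markers (−0.024) below 0. The number of lists above the random range was 7 to 10 and below it 10 or 11, and the 10 lists below were below under all 12 alternatives. The naming rule selected 139 genes, of which 101 were called, and 0 of these called genes changed direction. Called genes named outside that rule were not followed one by one. Signal over background limits the dim genes: 71 called genes had only a bound in 1 RNA, 41 higher and 30 lower.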

Other observations

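The mitochondrial genome list and the tests on T cell receptor genes (first 1 test, later split in 2), on antigen-presenting cells and on the genes around Lamtor1 were chosen only after their results were seen, while the tests on tRNA synthetases and on the proton pump followed the main results but were set before their own values were seen.

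Most transcripts of the mitochondrial genome leaned higher in the KO extract. Of 12 measured mitochondrial genes 4 were at least 2-fold higher on both arrays (ND4 1.34, CYTB 1.33, ND4L 1.28 and ND1 1.28), 11 lay above 0 on both arrays, COX1 lay at 0.30, COX2 at 0.38 and ND6 at −0.34. Their median of 1.03 was 0.41 under median centring, or 0.79 relative to all measured genes. A difference from the nuclear genes of oxidative phosphorylation was not tested.

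Most tRNA synthetase genes of the Atf4 list were lower in the KO extract, and other cytosolic synthetases leaned the same way: 5 of 14 were at least 2-fold lower, with Cars at −1.54 and Iars at −1.32 (median −0.64, percentile 0.06 of random lists). The 16 measured mitochondrial synthetases had 0 called (median −0.17, percentile 15.5). The hypothesis was that the difference is confined to the cytosolic enzymes. The medians differed by −0.47, between the limits of −0.5 and −0.2 set for and against it, so the hypothesis stays open. They lay further apart with the processed signals (−0.74 against −0.19) and under median centring (−1.20 against −0.45), past the limit for the hypothesis, and short of it with the other 2 alternatives (−0.64 against −0.19 with no background subtraction and −0.64 against −0.20 with an offset of 1).

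Of 14 proton pump (V-ATPase) genes outside the lysosome list 10 were measured, and all 10 lay above 0 on both arrays. Atp6v0b stood at 1.11 and Atp6v1e1 at 1.07, and 0 were past the rule of size. Under median centring not all of the 10 lay above 0, and the lowest stood at −0.45. Their median of 0.64 lay at percentile 99.96 of random lists (0.12 under median centring, 0.50 relative to all measured genes). This is consistent with the hypothesis that the measured pump genes, and not only its 2 called subunits, may be expressed at a higher level in the KO extract; whether TFEB-family factors are involved was not tested.

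Cd4 was lower (−1.18) and 6 of 13 markers of CD8 T, NK and gamma-delta T cells were higher in the KO extract. Replacement of most alpha-beta T cells by gamma-delta T or NK cells would lower the alpha and beta receptor constant genes about as far. TRAC, TRBC1 and TRBC2 had a median of −0.15 (TRAC 0.66), which argues against it. Under median centring the median was −0.80, or −0.43 relative to all measured genes. The −0.80 lay between the test's limits for and against, so the outcome depends on the normalization. All 10 measured probes of gamma and delta receptor segments, or 100%, were higher on both arrays, against 7 of 33 alpha and beta probes. TRDC stood at 2.75 and TRGC1 at 2.78. A probe counted as measured if it was well above background in at least 1 RNA. A segment dim in WT could thus enter only when bright in KO, so the filter favours such a count. An admixture of gamma-delta T cells may have been present in the KO culture. The CD4+CD62L+ sort would remove most of them, however, and Sox13, another marker, was at 0.02. Transcription of these segments in CD4+ T cells of the KO, a biological difference, was not tested and stays open. The share of gamma-delta T cells was not estimated, and the cause of the lower Cd4 stays open. S100a8, S100a9 and Fcer1g were higher in the KO extract. Macrophages or dendritic cells would bring their abundant transcripts, but Lyz2 (0.62, not well above background in WT), Cst3 (−0.49), Cd74 (0.19), H2-Ab1 (−1.90) and H2-Eb1 (−0.75) had a median of −0.49 (−1.07 under median centring, or −0.70 relative to all measured genes). This does not exclude a small share of such cells, since only 2 of these 5 genes were above background in both RNAs and under the median WT level, and Lyz1 and Tyrobp were higher in KO (at least 2.97-fold and 4.30-fold). Neutrophils, which the sort and the 5 day culture would mostly remove, and expression by the T cells themselves were not tested.

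Genes near Lamtor1 leaned lower in the KO extract. Of 63 measured genes within 3 Mb, 10 were at least 2-fold lower (15.9%, against 6.89% of all measured genes) and 0 higher, with Map6 (−3.57), Trim12a (−3.30) and Rrm1 (−1.65) the lowest. Among named genes closest to the Lamtor1 probe, Clpb (−1.18), Inppl1 (−1.52) and Anapc15 (−1.10) were called lower. Lrrc51 (−0.78), Rnf121 (−0.42), Il18bp (−0.04) and Numa1 (0.52), also close to it, were not called. The median of the 63 genes, −0.37, lay at percentile 1.25 of 1604 overlapping windows of 6 Mb elsewhere in the genome, and was −0.71 under median centring, or −0.34 relative to all measured genes. A candidate explanation is a chromosome segment of another strain carried along with the targeted allele, which these arrays cannot show directly. The window also holds genes of the cell cycle and of the interferon response, which were lower elsewhere too, so the 2 explanations overlap.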
